A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

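Gene counts of ribosome footprints were taken as deposited by the authors, 1 count per gene and library for 12 libraries of yeast W303 Ade+. According to the labels' protocols, duplicate pre-cultures were grown overnight at 30 °C and diluted into main cultures, which were grown further until their OD600 reached 0.5. Each main culture was split into cultures of 200 ml that were kept for 10 min at 30, 40 or 42 °C, filtered and flash-frozen. RNA was isolated with hot acid phenol, and footprint libraries followed published protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.17, Bowtie2 2.2.6 and STAR 2.5.2b and the genome build R64. The roles and order of these programs, the strand setting and the rule by which reads were counted are not given in the sources used here. No read was realigned, and no matched RNA sequencing was used here.

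The count table had 6697 genes. Of these, 6014 identifiers were found in the R64 annotation and 683 were not, and the latter held 0.04% to 0.112% of the counts of a library. Symbols, chromosomes, starts and ends came from that annotation. Sequence shared between genes was measured as the share of 28-mers of a coding sequence that occur in another coding sequence. In 189 genes this share was at least 20%, and such genes are marked as uncertain where they are first named.

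Groups, comparisons, settings and gene lists were chosen before the data were examined. Differential counts were tested with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values scaling, 1 mean per group and robust quasi-likelihood F tests. Genes were kept by the filter for expression with a minimum count of 10 and a total of 15, which left 5719 of 6697. The fit had 6 residual degrees of freedom and a median prior of 25.5. In all, 11 comparisons were drawn from this fit: each heated group with 30 °C and 42 °C with 40 °C in each strain, IDRm with WT at each temperature, and the difference between the strains in the change from 30 °C to 40 or 42 °C. The p-values of each comparison were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p of at most 0.05. Standard errors of log2 fold changes were computed as the absolute change divided by the square root of its F statistic. They are therefore approximate. Levels are CPM on the scaled library sizes, with the mean and standard deviation of 2 libraries, and log2 levels used a prior count of 2.

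There were 39 fixed gene lists, written from general knowledge of yeast genes. The 38 with at least 5 measured members were tested, and the alpha-cell list with 3 measured members was not. The lists cover chaperones of the cytosol, mitochondria and endoplasmic reticulum, chaperones at the ribosome, general stress, trehalose and glycogen, antioxidants, ribosomal proteins of cytosol and mitochondria, ribosome biogenesis, RNA polymerases I and III, translation factors, tRNA synthetases, and amino acid, sulfur, purine, sugar, sterol and energy metabolism. They also cover the proteasome, cell wall, secretory pathway, transport, histones, cell cycle, granules and mRNA decay, autophagy, phosphate, iron, mating type, pheromone response, meiosis and auxotrophic markers. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. They were also tested with fry. The p-values of each method were adjusted by the Benjamini-Hochberg method over the lists of a comparison. For each list the genes called in the adjustment over all genes were counted, and again those called when adjusted over the list alone.

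Genes are named by a fixed rule. In each comparison the 6 highest and 6 lowest changes were taken among called genes with a mean of at least 20 CPM and the same direction in both replicate numbers. For each list described, up to 3 called members with the largest changes were added, or, where none passed, up to 2 with the highest level. DED1, HSP104, SSA4, HSP26, HSP12, HSP82, SSA1, PAB1, TEF1, PMA1, ADH1 and PGK1 were always added. In the comparisons of 42 with 40 °C and of temperatures within IDRm fewer genes are named, and some genes of the differences of responses are given in the closing part alone. Uncharacterised and dubious frames that overlap other genes were counted but need not be named. A further gene that the rule names is not reported here.

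Each result was recomputed with other settings. These were scaling by the DESeq2 size factors or by library size alone, no filter, a fit of the libraries of a comparison alone, the Wald test of DESeq2 1.42.0, replicate blocks, a minimum change of 2-fold, and each library left out in turn. After the data had been seen, 2 settings were added: a glmTreat test against 1.5-fold, and a count without genes that share 28-mers. The power of the tests was checked with known changes put into simulated counts. These were drawn from a common mean per gene over all groups and the fitted dispersions. They follow the model of the test, so the shares below need not hold for the deposited counts. For IDRm against WT at 42 °C, 67.7%, 91% and 100% of planted changes of 1.5-, 2- and 4-fold were recovered, and 4.47% of the calls were false. For the difference of responses to 42 °C the shares were 53.8%, 77.6% and 93.8%, with 4.52% false, and for WT at 42 against 30 °C 78.8%, 87.7% and 98.5%, with 5.98% false. All 5 planted sets of 20 genes were called by each list method. Of 45 unchanged sets, camera at the preset correlation called 1 and fry 1 for IDRm against WT at 42 °C. For the difference of responses to 42 °C fry called 1 of 45. Genes were drawn independently, so this check cannot show how the list tests deal with correlated genes. Relations across genes are given as correlations and total least squares slopes over genes with at least 10 CPM, without p-values, because genes are not independent replicates.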

Results

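Ribosome footprints, the short RNA fragments that translating ribosomes protect from nuclease, were counted per gene in 12 libraries of budding yeast. The cells were haploid laboratory yeast of the W303 Ade+ background in which Ded1, a DEAD-box RNA helicase of translation initiation, carried the red fluorescent protein mCherry. The WT strain had Ded1-mCherry and the other strain Ded1_IDRm-mCherry, a variant named IDRm here as the labels give it. Each strain was grown at 30 °C, divided, and kept for 10 min at 30, 40 or 42 °C, which gave 6 groups of 2 libraries. The replicates came from duplicate pre-cultures, and each main culture was split over the temperatures. The p-values measure the spread between replicate libraries, pooled over the groups and moderated by that of other genes. They treat the 12 libraries as independent. No spike-in was recorded, so every level is a share of its library, and no matched RNA sequencing was analysed here, so translational efficiency is not given.

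In WT the 30 °C libraries held 7851819 and 3429950 counts, those at 40 °C 3976811 and 5357187, and those at 42 °C 5958521 and 3979334. In IDRm the totals were 5102189 and 5717879 at 30 °C, 4526976 and 4617567 at 40 °C, and 4412003 and 4084186 at 42 °C. Between 5999 and 6286 genes had at least one count in a library, and the 10 most abundant genes took 14.6% to 21.3% of the counts. Replicates had Pearson correlations of log2 CPM (counts scaled to library size) of 0.9894 to 0.9942. Principal components 1 and 2 held 76.1% and 13.1% of the variance and separated the temperatures, and component 3, with 4.82%, had positive scores in every WT library and negative scores in every IDRm library. The replicates of WT at 30 °C differed in heat-induced genes: HSP26 had 71.32 ± 61.7 CPM, SSA4 320.7 ± 231 CPM and HSP104 887 ± 257 CPM (mean ± SD, n = 2). Each gene had 1 dispersion over all groups, so the standard errors of these genes were large in every comparison, also at 40 and 42 °C. Levels are mean CPM ± SD with n = 2, and changes are log2 fold changes ± approximate standard error between groups of 2 libraries.

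DED1 (YOR204W, chromosome XV, 722911 to 724725 in R64), the gene that carries the tag and the variant, was read in every group. In WT it had 1404 ± 32.5 CPM at 30 °C, 1317 ± 4.16 CPM at 40 °C and 1369 ± 125 CPM at 42 °C, and in IDRm 1431 ± 6.93, 1075 ± 32.3 and 1301 ± 42.2 CPM. The strains differed at 40 °C, by −0.29 ± 0.07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00148). In edgeR they did not differ detectably at 30 °C (0.03 ± 0.07, adjusted p = 0.834) or 42 °C (−0.07 ± 0.07, adjusted p = 0.423). Both strains express DED1, so these counts do not check which allele a library carried.

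The first question was which genes gained or lost footprints when WT cells were moved to 40 °C. Heat-inducible chaperones and general stress genes rose most: HSP12, a small membrane-stabilising stress protein, rose from 23.57 ± 14.1 to 2745 ± 324 CPM. HSP104 (YLL026W, chromosome XII, 88623 to 91349), the protein disaggregase, rose from 887 ± 257 to 28730 ± 773 CPM. Ribosome biogenesis genes fell most: NSR1 (YGR159C, chromosome VII, 806412 to 807656), a nucleolar protein of pre-rRNA processing, fell from 380 ± 99.3 to 3.763 ± 0.596 CPM. PAB1 (YER165W, chromosome V, 510373 to 512106), the poly(A)-binding protein, fell from 1731 ± 3.52 to 375.8 ± 7.85 CPM. Of 5719 genes tested, 2062 were higher and 2257 lower at 40 °C than at 30 °C, and 1170 and 1066 of these changed at least 2-fold. With library size alone as the scale, 1620 were higher and 2739 lower, since that scale moved the median gene by −0.24 on the log2 scale.

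Of 25 heat-inducible cytosolic chaperones, 24 rose and 1 fell, also when adjusted over the list alone, with a median of 3.46 (camera, adjusted p = 1.9e-18; adjusted p = 0.107 with an estimated correlation). HSP26 and HSP42, small heat shock proteins, changed by 6.97 ± 0.62 and 6.65 ± 0.58, SSA4, an inducible Hsp70, by 6.26 ± 0.60, HSP82, an Hsp90, by 5.11 ± 0.20 and HSP104 by 5.02 ± 0.23. SSA1, a second Hsp70, rose by 3.43 ± 0.08, with counts partly shared with a near-identical paralog. HSP30, a membrane heat shock protein, changed by 6.92 ± 0.89 (edgeR, adjusted p = 0.000358), but had an adjusted p = 0.0594 when the 4 libraries of the comparison were fitted alone. All 37 general stress genes, those of the Msn2 and Msn4 type, rose, also adjusted over the list alone, with a median of 4.48 (camera, adjusted p = 1.17e-40; adjusted p = 0.107 with an estimated correlation). Among them HSP12 changed by 7.04 ± 0.40, PHM7 by 6.93 ± 0.18 and CTT1, the cytosolic catalase, by 6.79 ± 0.40. YNL194C, a membrane protein outside the lists, rose by 6.98 ± 0.18. Trehalose and glycogen genes rose in 14 of 15 cases, among them PGM2, phosphoglucomutase, by 6.57 ± 0.38 and TSL1, a subunit of trehalose synthase, by 5.72 ± 0.34 (adjusted p = 0.142 with an estimated correlation). Of 20 antioxidant genes 16 rose and 1 fell (adjusted p = 0.16 with an estimated correlation). Both lists gave the same numbers adjusted over the list alone.

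Endoplasmic reticulum folding genes rose in 11 of 13 cases and fell in 1 with a median of 0.83, including KAR2, the lumenal Hsp70, 8-fold, and ERO1, the disulfide oxidase, by 3.80 ± 0.10 (adjusted p = 0.107 with an estimated correlation). Mitochondrial chaperones were split, with 6 higher and 4 lower of 12, and HSP78 and MDJ1 at 6.10 ± 0.51 and 3.95 ± 0.13 (adjusted p = 0.27 with an estimated correlation). Autophagy and vacuolar protease genes rose in 12 of 13 cases, with ATG8 at 2.66 ± 0.13 and PRB1 at 2.28 ± 0.07 (adjusted p = 0.169 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 26 of 37 cases and lower in 2, or 26 and 3 adjusted over the list alone (adjusted p = 0.444 with an estimated correlation). Glycolysis genes were higher in 15 and lower in 1 of 17 (adjusted p = 0.529 with an estimated correlation), a call that ended without the genes that share sequence (adjusted p = 0.187). PGK1 and ADH1, abundant enzymes of that pathway, rose by 1.08 ± 0.07 and 0.63 ± 0.08. Glyoxylate and diauxic genes were higher in 12 of 14 cases, or 13 adjusted over the list alone (adjusted p = 0.181 with an estimated correlation), a call that ended without WT 40 °C replicate 1 (adjusted p = 0.0639). Of 7 hexose transporters 4 rose and 2 fell, with HXT5 at 6.53 ± 0.16 and HXT1 at −1.61 ± 0.11 (adjusted p = 0.16 with an estimated correlation), a call that ended without WT 30 °C replicate 2 (adjusted p = 0.0705) and without the genes that share sequence (adjusted p = 0.1).

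Of 113 ribosome biogenesis genes, 112 fell, also adjusted over the list alone, with a median of −2.75 (camera, adjusted p = 1.06e-48; adjusted p = 0.123 with an estimated correlation). NSR1 fell by 6.61 ± 0.38, CIC1 by 5.88 ± 0.17 and UTP9 by 5.17 ± 0.18. REI1, ALB1 and SOF1, which act in ribosome assembly, fell by 5.48, 5.19 and 5.14. Of 136 cytosolic ribosomal proteins 130 fell and 2 rose, with a median of −1.16 and RPS9A at −2.35 ± 0.08 (camera, adjusted p = 6.04e-25; adjusted p = 0.197 with an estimated correlation). RNA polymerase I and III subunits fell in 19 of 20 cases, including RPA43 by 4.78 ± 0.18 (adjusted p = 0.142 with an estimated correlation). Translation initiation factors fell in 25 of 29 cases and rose in 1, the former including NIP1, an eIF3 subunit, by 2.77 ± 0.08, TIF5 by 2.64 ± 0.09 and PAB1 at −2.202 ± 0.07 (adjusted p = 0.181 with an estimated correlation). Elongation and termination factors fell in 9 and rose in 2 of 13, with SUP45, release factor eRF1, at −2.66 ± 0.09 (adjusted p = 0.197 with an estimated correlation). tRNA synthetases fell in 17 and rose in 1 of 18 cases, with ALA1 at −2.63 ± 0.07 (adjusted p = 0.242 with an estimated correlation). Ribosome-bound and TRiC or prefoldin chaperones fell in 15 and rose in 1 of 21, with CCT5 at −2.36 ± 0.09 (adjusted p = 0.142 with an estimated correlation). These 6 lists gave the same numbers adjusted over the list alone. PMA1, the plasma membrane proton pump, was at −0.17 ± 0.07 (edgeR, adjusted p = 0.0258), a call that ended without WT 30 °C replicate 2 (adjusted p = 0.166) or WT 40 °C replicate 1 (adjusted p = 0.208) and under 3 other settings. TEF1, elongation factor 1A, was at −0.16 ± 0.08 (adjusted p = 0.0894), with counts shared with its copy TEF2.

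Among metabolic and regulatory lists, purine and one-carbon genes fell in 17 of 19 cases with a median of −1.91, among them IMD4 by 3.75 ± 0.10 and ADE17 by 3.53 ± 0.09 (adjusted p = 0.107 with an estimated correlation). Sulfur and methionine genes fell in 14 and rose in 1 of 19 cases, with MET6, methionine synthase, at −3.30 ± 0.09 (adjusted p = 0.197 with an estimated correlation). Amino acid biosynthesis genes fell in 31 and rose in 4 of 43, with ILV5 at −3.47 ± 0.09 (adjusted p = 0.302 with an estimated correlation). Phosphate genes fell in 11 and rose in 2 of 13 cases, with PHO89 at −2.64 ± 0.12, while PHM8, a lysophosphatidic acid phosphatase, rose 21.9-fold (adjusted p = 0.107 with an estimated correlation). Cell cycle regulators fell in 15 and rose in 3 of 23 cases, with CLB2, a mitotic cyclin, at −3.43 ± 0.20 (adjusted p = 0.41 with an estimated correlation). Granule and mRNA decay proteins fell in 16 and rose in 2 of 21, with EDC3 at −2.29 ± 0.14 (adjusted p = 0.242 with an estimated correlation). Translocation and glycosylation genes of the endoplasmic reticulum fell in 15 and rose in 2 of 19 cases, with OST1 at −2.03 ± 0.10 (adjusted p = 0.181 with an estimated correlation). The a-cell genes fell in 5 and rose in 1 of 7, with STE6, the a-factor exporter, at −2.41 ± 0.10 (adjusted p = 0.169 with an estimated correlation). Adjusted over the list alone, the counts of these 8 lists were the same except for 1 higher purine gene.

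The remaining lists did not pass camera at 40 °C with all libraries (adjusted p of 0.068 to 0.967). Mitochondrial ribosomal proteins had 2 higher and 32 lower of 65, or 1 and 31 adjusted over the list alone, and mitochondrially encoded genes 6 higher of 8. The tricarboxylic acid cycle list had 7 higher and 3 lower of 10, and passed without WT 30 °C replicate 1 (camera, adjusted p = 0.0154). Ergosterol had 6 and 12 of 23, cell wall 15 and 5 of 22, or 16 and 5 adjusted over the list alone, plasma membrane transport 7 and 9 of 19, histones 6 and 1 of 10 and iron genes 7 and 2 of 13. The proteasome list had 9 higher and 11 lower of 35, with RPN4, its transcription factor, higher by 3.47 ± 0.09. Pheromone pathway genes had 4 higher and 7 lower of 12, meiosis genes 11 higher of 15 and auxotrophic markers 5 lower of 8. The alpha-cell list, with 3 measured genes, was too short to test. None of the 26 list calls of this comparison was kept with an estimated correlation, while all 26 passed fry, which tests whether genes of a list move one way and does not compare them with other genes. Of the uncalled lists tested, all but plasma membrane transport and the proteasome (fry, adjusted p = 0.4 and 0.109) passed fry too. Passing fry thus did not set the 26 calls apart.

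The second question was what WT cells translated after 10 min at 42 °C. Several chaperones rose here too, with HSP42 at 5.94 ± 0.56, APJ1, an Hsp40, at 5.67 ± 0.25 and HSP104 at 3.87 ± 0.22. MGA1, a heat shock factor-like protein, rose by 6.40 ± 0.26 and the uncharacterised frame YPR145C-A by 5.97 ± 0.22. Among the largest decreases, NCE103, carbonic anhydrase, fell by 4.28 ± 0.13, ADE17 by 4.16 ± 0.09 and ACC1, acetyl-CoA carboxylase, from 3019 ± 67.7 to 298.9 ± 2.1 CPM. MIG2, a glucose repressor, fell by 3.46 ± 0.17, PYC1, pyruvate carboxylase, by 3.07 ± 0.08 and ALB1 by 2.99 ± 0.15. PAB1 fell by 1.166 ± 0.07, to 771.1 ± 4.86 CPM. Against 30 °C, 1716 genes were higher and 1919 lower, with 836 and 495 changed at least 2-fold.

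Of the 25 heat-inducible chaperones 23 rose and 1 fell, also adjusted over the list alone, with a median of 2.51 (camera, adjusted p = 1.29e-21; adjusted p = 0.154 with an estimated correlation). SSA4 rose by 4.99 ± 0.57, HSP82 by 4.07 ± 0.19 and SSA1 by 2.51 ± 0.08. BTN2, HSP30 and HSP26 changed by 6.28 ± 0.80, 5.92 ± 0.86 and 5.15 ± 0.58, and with the 4 libraries alone their adjusted p was 0.0676, 0.0865 and 0.0532 (edgeR). All 37 general stress genes rose, also adjusted over the list alone, with a median of 2.26 and with SOL4 at 5.48 ± 0.23, PHM7 at 5.29 ± 0.20, TSL1 at 5.15 ± 0.33 and HSP12 at 2.90 ± 0.40 (adjusted p = 0.265 with an estimated correlation). Iron genes rose in 11 of 13 cases, or 12 adjusted over the list alone, with TIS11 at 3.31 ± 0.18 and the siderophore transporter SIT1 at 2.15 ± 0.14 (adjusted p = 0.386 with an estimated correlation). Meiosis genes rose in 12 of 15 cases, also adjusted over the list alone, with IME1, the meiotic activator, at 2.495 ± 0.21 (adjusted p = 0.475 with an estimated correlation), a call that ended without WT 30 °C replicate 1 (adjusted p = 0.143). RPN4 rose by 4.11 ± 0.09.

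Ribosome biogenesis genes fell in 90 of 113 cases and rose in 4, the same adjusted over the list alone, with a median of −0.61, NSR1 at −2.52 ± 0.23 and SOF1 at −2.17 ± 0.13 (camera, adjusted p = 1.94e-09; adjusted p = 0.491 with an estimated correlation). Cytosolic ribosomal proteins had 74 lower and 15 higher of 136, a median of −0.18 and no list call (camera, adjusted p = 0.0831), though the list passed without WT 30 °C replicate 2 (adjusted p = 0.0215) or WT 42 °C replicate 2 (adjusted p = 0.0173). Purine and one-carbon genes fell in 18 and rose in 1 of 19 cases, with SHM2 at −2.73 ± 0.08 (camera, adjusted p = 4.21e-28; adjusted p = 0.0977 with an estimated correlation). Sulfur genes fell in 14 of 19 cases. Amino acid biosynthesis genes fell in 35 and rose in 1 of 43, or 36 and 1 adjusted over the list alone. Members of these lists were MET6 at −2.54 ± 0.08 and CPA1 at −2.74 ± 0.14 (adjusted p = 0.386 for both lists with an estimated correlation). Granule and decay proteins fell in 15 and rose in 1 of 21 cases, or 16 and 1 adjusted over the list alone. Cell cycle regulators fell in 17 and rose in 2 of 23. Members of these lists were LSM1 at −1.68 ± 0.12 and CLB2 at −2.71 ± 0.17 (adjusted p = 0.386 and 0.45 with an estimated correlation). TEF1 and PGK1 rose by 0.40 ± 0.08 and 0.32 ± 0.07, and PMA1 was at −0.24 ± 0.07 (edgeR, adjusted p = 0.00259; 0.0589 with the 4 libraries alone). DED1 and ADH1 did not change detectably, at −0.04 ± 0.07 and −0.12 ± 0.08 (edgeR, adjusted p = 0.648 and 0.18). In this comparison 19 lists passed camera and none was kept with an estimated correlation.

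The hotter temperature was also compared with 40 °C directly. In WT, ribosome biogenesis genes had more footprints at 42 °C than at 40 °C in all 113 cases and cytosolic ribosomal proteins in 131 of 136 and fewer in 1, with medians of 2.16 and 0.96 and CIC1, NSR1 and UTP9 at 4.50 ± 0.20, 4.09 ± 0.46 and 3.80 ± 0.21. General stress genes were lower in 35 of 37 cases, with a median of −1.82 and HSP12 at −4.14 ± 0.32 (adjusted p = 0.131 for each of these 3 lists with an estimated correlation, and the same counts adjusted over the list alone). HXT5 was at −3.57 ± 0.12. HSP104 was lower by 1.16 ± 0.20 and PAB1 higher by 1.04 ± 0.07, and DED1 was at 0.06 ± 0.07 (edgeR, adjusted p = 0.505). There were 1703 genes higher and 1684 lower, or 50.3% higher. With library size alone as the scale 2620 were higher and 921 lower, or 74%, since that scale moved the median gene by 0.31 on the log2 scale.

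IDRm cells were compared across temperatures in the same way. At 40 °C against 30 °C, 2137 genes were higher and 2284 lower. The higher genes were 48.3% of the calls, or 39.6% with library size alone, which moved the median gene by −0.227. BTN2, HSP26 and HSP12 were at 7.22 ± 0.83, 7.15 ± 0.62 and 6.93 ± 0.38, and NSR1, CIC1 and PAB1 at −7.01 ± 0.35, −6.36 ± 0.17 and −3.12 ± 0.07. Heat-inducible chaperones rose in 24 of 25 cases and fell in 1, general stress genes in all 37, and all 113 ribosome biogenesis genes fell (adjusted p = 0.0681, 0.0681 and 0.126 with an estimated correlation; the same counts adjusted over the list alone). DED1 fell by 0.41 ± 0.07 (edgeR, adjusted p = 2.09e-06). At 42 °C against 30 °C, 2104 were higher and 2098 lower, with TOS8 at 6.59 ± 0.22, HSP104 at 4.08 ± 0.22, IMD4 at −4.71 ± 0.11, OST1 at −3.79 ± 0.12 and PAB1 at −3.09 ± 0.07. General stress genes rose in all 37 cases and ribosome biogenesis genes fell in 111 of 113 (adjusted p = 0.0782 and 0.333 with an estimated correlation; the same counts adjusted over the list alone). At 42 °C against 40 °C, 1564 were higher and 1546 lower, or 2228 and 974 with library size alone, which moved the median gene by 0.21. General stress genes were lower in 35 and higher in 1 of 37 cases and ribosome biogenesis genes higher in 110 of 113 (adjusted p = 0.122 for both with an estimated correlation; the same counts adjusted over the list alone), and PAB1 was at 0.03 ± 0.07 (edgeR, adjusted p = 0.801).

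**Figure D1:**
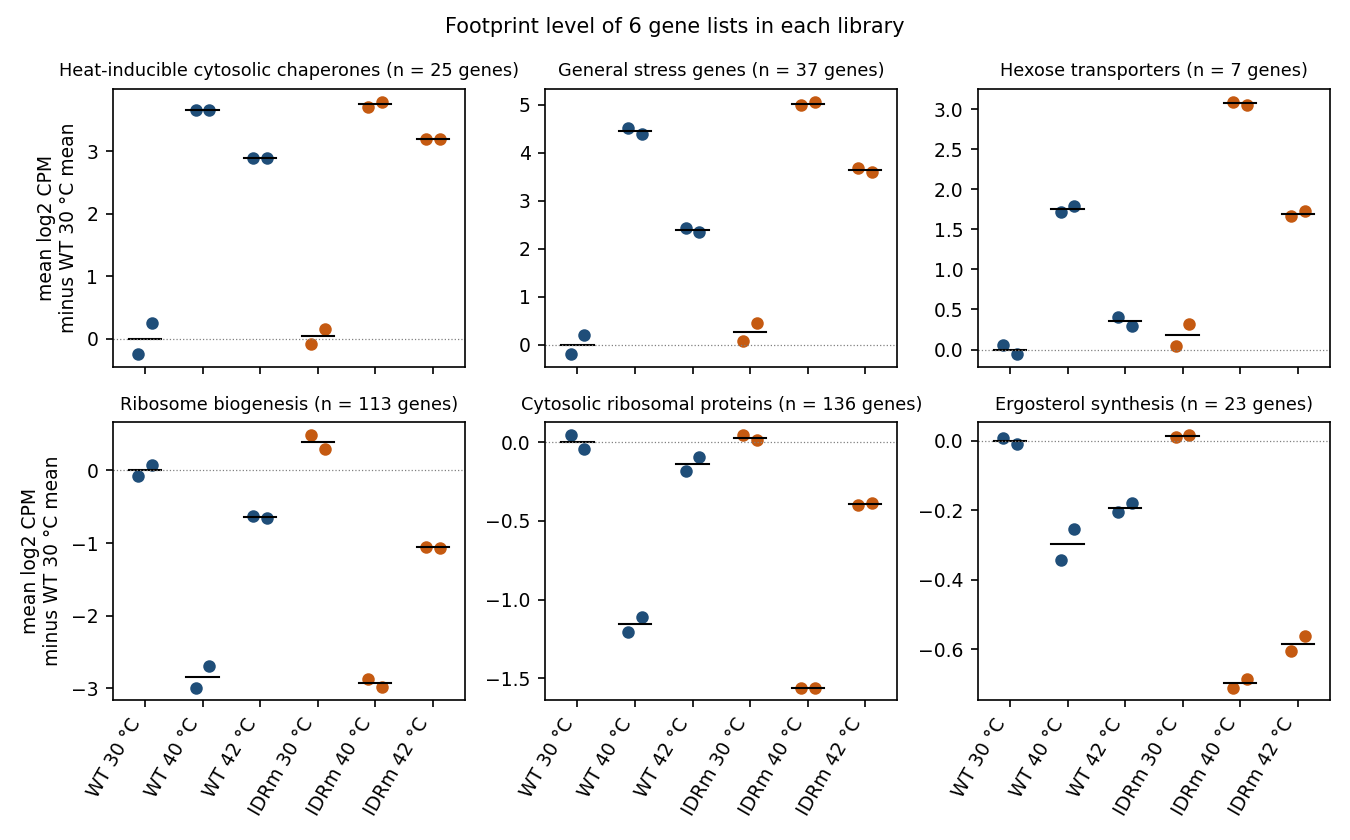
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of the WT 30 °C libraries. Columns are the 6 groups of strain and temperature in °C. Dots are libraries, short black lines are group means, blue is WT and orange IDRm. At 40 °C the means of the 37 general stress genes and the 25 heat-inducible chaperones lay above the 30 °C mean of the same strain. The mean of the 113 ribosome biogenesis genes lay below it, in both strains.

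The third question was how the strains differed before heating. At 30 °C, 548 genes were higher and 386 lower in IDRm than in WT, with 38 and 48 changed at least 2-fold. MEP2 (YNL142W, chromosome XIV, 357453 to 358952), an ammonium permease, was at 148.1 CPM in WT and 34.98 CPM in IDRm, a change of −2.06 ± 0.11 (edgeR, adjusted p = 1.7e-14). GAP1, the general amino acid permease, fell by 1.497 ± 0.07 and HO, the mating-type endonuclease, which laboratory strains carry in an inactive form, by 1.94 ± 0.15. SNZ1, of vitamin B6 synthesis, rose by 1.53 ± 0.09, ADR1, a regulator of ethanol use, by 1.46 ± 0.12, PIR3, a cell wall protein, by 1.38 ± 0.12 and PDH1 by 1.21 ± 0.14. INO1, inositol phosphate synthase, was at 1.69 ± 0.18 (edgeR, adjusted p = 0.000137; 0.0505 with the 4 libraries alone), and the calls of TPO2, which shares sequence with a paralog and is uncertain, and the small frame YJL047C-A ended without either IDRm 30 °C replicate. Without IDRm 30 °C replicate 1, 231 genes were higher and 136 lower. Without WT 30 °C replicate 1 the counts were 325 and 251, and without IDRm 30 °C replicate 2 236 were lower.

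Sulfur and methionine genes fell in 12 of 19 cases, also adjusted over the list alone, with a median of −0.81 (camera, adjusted p = 1.79e-25; 0.0354 with an estimated correlation). MET3, ATP sulfurylase, fell by 1.78 ± 0.11, MHT1 by 1.56 ± 0.15, MET1 by 1.47 ± 0.17 and STR3 by 1.45 ± 0.15. The a-cell genes fell in 6 of 7 cases, or 7 adjusted over the list alone, with MFA1 and MFA2, the a-factor genes, at −0.72 ± 0.12 and −0.64 ± 0.10 and BAR1, the alpha-factor protease, at −0.67 ± 0.08 (camera, adjusted p = 7.61e-10; 0.0198 with an estimated correlation). Pheromone pathway genes fell in 6 of 12 cases, also adjusted over the list alone, with AGA1, the a-agglutinin anchor, at −1.35 ± 0.13 and FAR1 at −0.55 ± 0.10 (camera, adjusted p = 1.32e-05; 0.0354 with an estimated correlation). These were the 3 of the 13 list calls at 30 °C that held with an estimated correlation.

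Ribosome biogenesis genes rose in 94 of 113 cases and fell in 1, or 103 and 1 adjusted over the list alone, with a median of 0.42 and RRP36 and DBP7 at 0.90 ± 0.14 and 0.68 ± 0.13 (camera, adjusted p = 1.57e-37; adjusted p = 0.313 with an estimated correlation). The 30 °C replicates stood apart in this list: replicate 2 was higher than replicate 1 in 108 of 113 genes in WT and in 1 of 113 in IDRm. Cell wall genes rose in 10 of 22 cases, or 11 adjusted over the list alone, with GSC2, a glucan synthase subunit, at 0.95 ± 0.07 (camera, adjusted p = 7.61e-10; adjusted p = 0.313 with an estimated correlation). General stress genes were higher in 11 and lower in 2 of 37 cases, or 13 and 3 adjusted over the list alone, with UBI4, polyubiquitin, at −1.404 ± 0.07 (camera, adjusted p = 0.0232; adjusted p = 0.734 with an estimated correlation). That call ended without WT 30 °C replicate 1 (adjusted p = 0.968) or IDRm 30 °C replicate 2 (adjusted p = 0.734). Heat-inducible chaperones had 1 higher gene of 25 and a median of 0.05, beside the spread of these genes in WT at 30 °C given above. Without WT 30 °C replicate 1 the list mean was −0.20 (adjusted p = 0.0111) and without replicate 2 it was 0.31 (adjusted p = 0.000282). HSP104 was at 0.23 ± 0.20, SSA4 at −0.17 ± 0.50, HSP26 at 0.06 ± 0.59, HSP12 at 0.70 ± 0.46, HSP82 at 0.37 ± 0.17 and SSA1 at 0.20 ± 0.07, none past the test (edgeR, adjusted p of 0.0565 to 0.969). PAB1, PMA1, TEF1, ADH1 and PGK1 did not differ detectably either, at −0.03, 0.04, 0.20, 0.06 and −0.13 (edgeR, adjusted p of 0.122 to 0.776). Cytosolic ribosomal proteins had 5 higher and 2 lower of 136, or 5 and 0 adjusted over the list alone, with a median of 0.02 that was −0.01 with library size alone. That list did not pass with all libraries (camera, adjusted p = 0.5) and passed without WT 30 °C replicate 1 (adjusted p = 0.00893).

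At 40 °C, 653 genes were higher and 831 lower in IDRm than in WT, with 74 and 72 changed at least 2-fold. The higher genes were 44% of the calls, 52.2% with DESeq2 size factors and 39.7% with library size alone. Which direction held more genes thus depended on the scale. RCK1, a protein kinase of the stress response, rose by 2.78 ± 0.20, SPG4 by 2.18 ± 0.11, MRK1, a glycogen synthase kinase, by 2.07 ± 0.17, OYE3 by 1.999 ± 0.18 and YKR075C by 3.23 ± 0.39 (edgeR, adjusted p = 0.000466). MEP2 fell by 2.93 ± 0.10, GAP1 by 1.88 ± 0.07, ERG13, HMG-CoA synthase, by 1.63 ± 0.08 and URA6 (YKL024C, chromosome XI, 392526 to 393140), uridylate kinase, from 84.9 ± 5.09 CPM in WT to 23.21 ± 4.82 CPM in IDRm. PAB1 was at 375.8 ± 7.85 CPM in WT and 194.4 ± 12.8 CPM in IDRm, a change of −0.95 ± 0.07, and PMA1 at −0.75 ± 0.07. Without WT 40 °C replicate 2, 364 were higher and 501 lower, without IDRm 40 °C replicate 2, 340 and 508, and without IDRm 40 °C replicate 1, 542 were lower.

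Hexose transporters rose in 6 of 7 cases, also adjusted over the list alone, with a median of 1.41 (camera, adjusted p = 1.63e-24; 0.00516 with an estimated correlation), the only one of 20 list calls at 40 °C that held with that estimate. HXT3 rose by 1.72 ± 0.08 and HXT6 and HXT7 by 2.73 ± 0.15 and 1.77 ± 0.10, though HXT6 and HXT7 are near-identical and HXT3 shares part of its sequence with paralogs, so all 3 are uncertain. Cytosolic ribosomal proteins were lower in 92 and higher in 3 of 136 cases, or 103 and 6 adjusted over the list alone, with a median of −0.35 and RPL24B at −1.41 ± 0.07 (camera, adjusted p = 1.29e-27; adjusted p = 0.369 with an estimated correlation). RPL11A and SSB1, at −1.61 ± 0.11 and −1.57 ± 0.08, share most of their sequence with a paralog and are uncertain. General stress genes were higher in 21 and lower in 1 of 37 cases, or 26 and 1 adjusted over the list alone, with RTN2 at 1.87 ± 0.14 and GSY2, glycogen synthase, at 1.21 ± 0.08 (adjusted p = 0.292 with an estimated correlation). Antioxidant genes were higher in 11 and lower in 2 of 20 cases, or 13 and 2 adjusted over the list alone, with GPX1 at 1.396 ± 0.14 (adjusted p = 0.229 with an estimated correlation).

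Ergosterol genes fell in 10 of 23 cases, or 11 adjusted over the list alone, with ERG2 and ERG20 at −1.36 ± 0.12 and −1.17 ± 0.07 (camera, adjusted p = 3.1e-09; adjusted p = 0.196 with an estimated correlation). Phosphate genes fell in 9 of 13 cases, with VTC4 at −0.67 ± 0.08 (adjusted p = 0.196 with an estimated correlation). Plasma membrane transport genes fell in 9 and rose in 1 of 19, or 11 and 1 adjusted over the list alone, with SNQ2 at −1.04 ± 0.09 (adjusted p = 0.249 with an estimated correlation). Initiation factors had 9 lower and 3 higher of 29, or 10 and 3 adjusted over the list alone, with TIF3, eIF4B, at −1.12 ± 0.09 and DBP1, the paralog of DED1, at 0.72 ± 0.15 (adjusted p = 0.592 with an estimated correlation), a call that ended without WT 40 °C replicate 2 (adjusted p = 0.067). Elongation factors fell in 7 of 13 cases, or 9 adjusted over the list alone, with EFB1 at −0.86 ± 0.07 (adjusted p = 0.388 with an estimated correlation). tRNA synthetases fell in 10 of 18, or 11 adjusted over the list alone, with CDC60 at −0.83 ± 0.07 (adjusted p = 0.422 with an estimated correlation). Heat-inducible chaperones had 4 higher and 2 lower of 25, or 4 and 1 adjusted over the list alone, and ribosome biogenesis genes 5 and 23 of 113, and neither list passed (camera, adjusted p = 0.197 for both), though the latter did without WT 40 °C replicate 1 (adjusted p = 0.00257) or IDRm 40 °C replicate 1 (adjusted p = 0.0413). HSP104, SSA4, HSP26, HSP12, HSP82 and SSA1 were at 0.17, 0.22, 0.24, 0.60, 0.19 and 0.11 and ADH1 and PGK1 at 0.02 and 0.00, none past the test (edgeR, adjusted p of 0.176 to 0.976). TEF1, at −0.28 ± 0.08 (edgeR, adjusted p = 0.0152), lost its call without any one of the 4 libraries (adjusted p of 0.0777 to 0.0932).

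At 42 °C the strains differed in more genes, with 1165 higher and 1183 lower in IDRm and 145 and 215 changed at least 2-fold. URA6 was at 79.53 ± 10.2 CPM in WT and 8.814 CPM in IDRm, a change of −3.16 ± 0.16 (edgeR, adjusted p = 9.56e-17). OST1 (YJL002C, chromosome X, 433221 to 434651), a subunit of oligosaccharyltransferase, fell by 2.54 ± 0.13, PDE2 (YOR360C, chromosome XV, 1013241 to 1014821), the high-affinity cyclic AMP phosphodiesterase, by 2.53 ± 0.15 and VIP1 (YLR410W, chromosome XII, 937541 to 940981), an inositol pyrophosphate synthase, by 2.35 ± 0.12. PAB1 was at 771.1 ± 4.86 CPM in WT and 197.8 ± 10.4 CPM in IDRm, a change of −1.96 ± 0.07 (edgeR, adjusted p = 5.63e-20). HSP12 (YFL014W, chromosome VI, 107256 to 107585) was at 155 ± 26.2 CPM in WT and 1021 CPM in IDRm, and HXK1, hexokinase 1, at 620.5 and 2838 CPM. With library size alone as the scale 813 genes were higher and 1587 lower, 33.9% higher against 49.6%, since that scale moved the median gene by −0.11.

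General stress genes were higher in 34 and lower in 1 of 37 cases, also adjusted over the list alone, with a median of 1.35 (camera, adjusted p = 2.6e-26; adjusted p = 0.195 with an estimated correlation). HSP12 changed by 2.71 ± 0.31, DDR2 by 2.28 ± 0.24, HXK1 by 2.19 ± 0.15 and CTT1 by 2.13 ± 0.29, and EGO4, SNZ1 and YER066C-A, outside the lists, by 2.80 ± 0.29, 2.59 ± 0.13 and 2.49 ± 0.19. Trehalose and glycogen genes rose in 10 of 15 cases, also adjusted over the list alone, with GSY2 at 1.51 ± 0.09 (adjusted p = 0.263 with an estimated correlation). Antioxidant genes were higher in 16 and lower in 1 of 20, or 17 and 1 adjusted over the list alone, with PRX1 at 1.27 ± 0.10 (adjusted p = 0.195 with an estimated correlation). Hexose transporters were higher in 5 and lower in 1 of 7 cases, also adjusted over the list alone, with HXT2 at 1.43 ± 0.09 and HXT7, which shares reads with HXT6, at 3.12 ± 0.16 (adjusted p = 0.195 with an estimated correlation). Amino acid biosynthesis genes were higher in 26 and lower in 4 of 43, or 26 and 5 adjusted over the list alone, with HIS5 at 1.10 ± 0.09 (adjusted p = 0.361 with an estimated correlation). Heat-inducible chaperones were higher in 13 and lower in 2 of 25 cases, also adjusted over the list alone, with a median of 0.35, SSE2 at 0.91 ± 0.08 and SSA1 at 0.30 ± 0.07 (camera, adjusted p = 0.00561; adjusted p = 0.49 with an estimated correlation). HSP104, SSA4, HSP26 and HSP82 were at 0.44 ± 0.20, 0.41 ± 0.47, 0.78 ± 0.47 and 0.38 ± 0.17 and did not pass (edgeR, adjusted p of 0.113 to 0.556).

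Ribosome biogenesis genes fell in 67 of 113 cases, or 68 adjusted over the list alone, with a median of −0.37 and MAK21 at −1.42 ± 0.10 (camera, adjusted p = 1.99e-10; adjusted p = 0.53 with an estimated correlation). Cytosolic ribosomal proteins were lower in 62 and higher in 7 of 136 cases, also adjusted over the list alone, with RPS12 at −1.59 ± 0.07 (adjusted p = 0.546 with an estimated correlation). Initiation factors were lower in 10 and higher in 2 of 29, also adjusted over the list alone, among them GCD7, eIF2B beta, at −2.22 ± 0.13, PAB1 and TIF3 at −1.34 ± 0.08 (adjusted p = 0.49 with an estimated correlation). Ergosterol genes were lower in 11 and higher in 4 of 23, or 12 and 5 adjusted over the list alone, with ERG2 at −2.08 ± 0.11 and ERG11, the target of azole drugs, at −1.67 ± 0.07 (adjusted p = 0.218 with an estimated correlation). Plasma membrane transport genes fell in 14 and rose in 1 of 19 cases, also adjusted over the list alone, with PMA1 (YGL008C, chromosome VII, 479910 to 482666) at −1.28 ± 0.07 and GAP1 at −1.71 ± 0.07. Translocation and glycosylation genes were lower in 10 and higher in 2 of 19, or 11 and 3 adjusted over the list alone, with STT3 at −1.31 ± 0.09 (adjusted p = 0.218 for both lists with an estimated correlation). Phosphate and iron genes fell in 9 of 13 cases each, while 1 phosphate gene rose, also adjusted over the list alone, with PHO89 at −0.85 ± 0.16, PHO12, uncertain for its shared sequence, at −2.37 ± 0.16 and FET3, the multicopper ferroxidase, at −1.20 ± 0.10 (adjusted p = 0.195 and 0.361 with an estimated correlation). FKS1, a glucan synthase subunit, was at −1.72 ± 0.08, ALA1 at −1.96 ± 0.08, MEP2 at −2.25 ± 0.10 and IMD4 at −2.16 ± 0.13. TEF1 was at −0.17 ± 0.08 and did not pass (edgeR, adjusted p = 0.118), ADH1 rose by 0.33 ± 0.08, and PGK1, at 0.21 ± 0.07 (edgeR, adjusted p = 0.0109), lost its call without WT 42 °C replicate 1 (adjusted p = 0.0829) or IDRm 42 °C replicate 2 (adjusted p = 0.122).

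**Figure D2:**
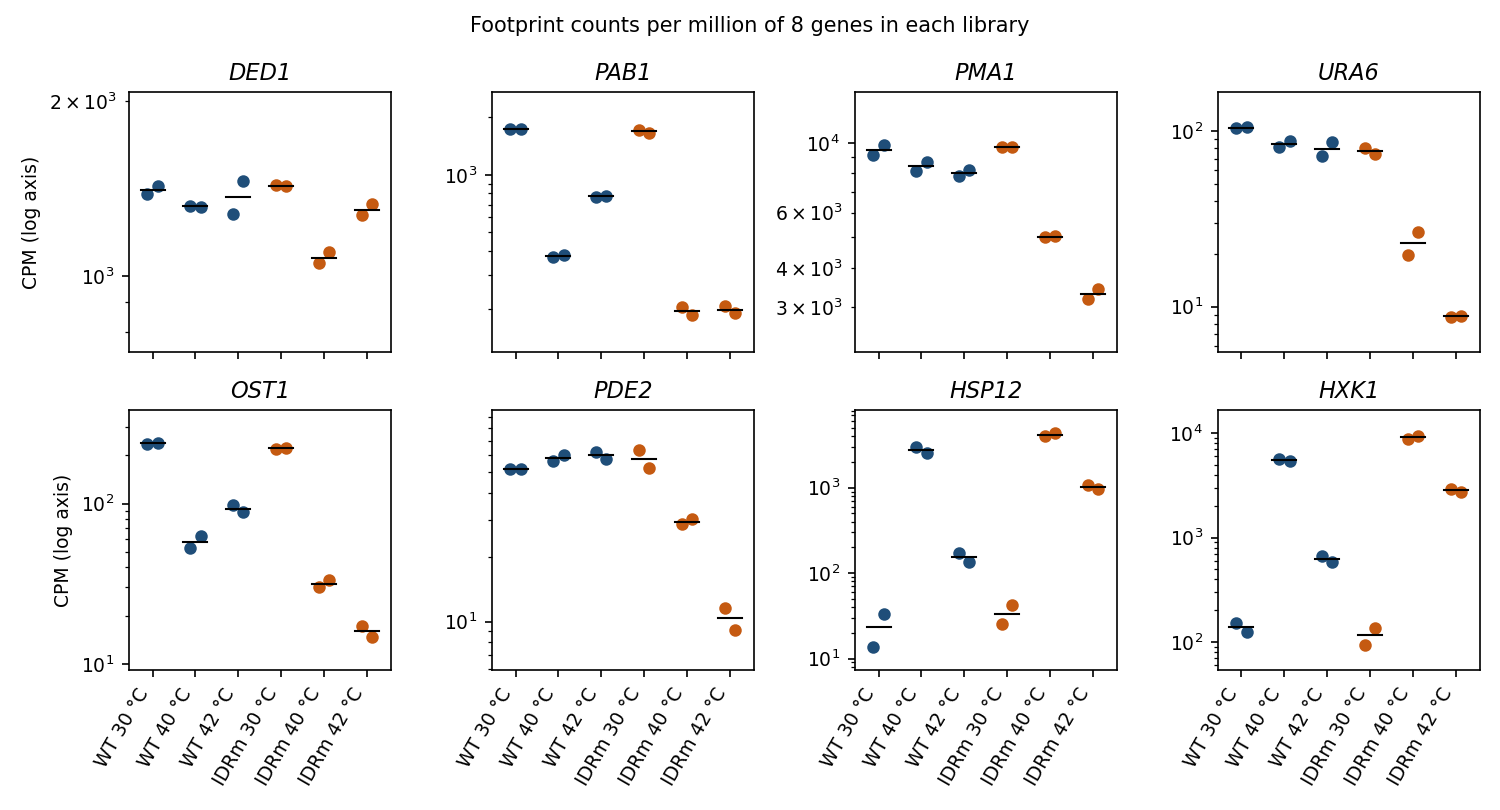
CPM, on a log axis, of 8 named genes in each of the 12 libraries by group of strain and temperature in °C. Dots are libraries, short black lines group means, blue WT and orange IDRm. PAB1, URA6, OST1 and PDE2 were lower and HSP12 and HXK1 higher in IDRm than in WT at 42 °C, while DED1 was at 1369 ± 125 and 1301 ± 42.2 CPM.

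The last question was whether the strains responded differently to heat, tested as the difference of their changes from 30 °C. For 40 °C, 218 genes had a more positive and 487 a more negative change in IDRm. SUC2, invertase, was at 1.96 ± 0.15, MTH1, a glucose-sensing regulator, at 1.77 ± 0.27 and FAT3 at 2.12 ± 0.38, and RPL24B, ERG13 and ERG2 at −1.49 ± 0.10, −1.49 ± 0.11 and −1.55 ± 0.14. PAB1 and PMA1 were at −0.92 ± 0.10 and −0.79 ± 0.09. DED1, at −0.32 ± 0.10 (edgeR, adjusted p = 0.0225), lost its call when any of 7 of the 8 libraries was left out (adjusted p of 0.0506 to 0.118). Ribosomal proteins had 75 more negative and 2 more positive changes of 136, or 88 and 2 adjusted over the list alone, and ergosterol genes 10 more negative of 23, or 11 (adjusted p = 0.239 and 0.152 with an estimated correlation). Hexose transporters had 5 more positive of 7, also adjusted over the list alone, with HXT3, uncertain as above, and HXT4 at 1.139 ± 0.11 and 1.41 ± 0.25 (adjusted p = 0.145 with an estimated correlation). HSP104, SSA4, HSP26, HSP12, HSP82, SSA1 and ADH1 were at −0.06, 0.40, 0.18, −0.10, −0.18, −0.09 and −0.04, none past the test (edgeR, adjusted p of 0.619 to 0.94), nor was PGK1 (adjusted p = 0.412). TEF1, at −0.48 ± 0.12 (edgeR, adjusted p = 0.00753), lost its call with library size alone (adjusted p = 0.0986). Without WT 40 °C replicate 2 the counts were 119 and 307, and without IDRm 30 °C replicate 1 or IDRm 40 °C replicate 2, 122 and 130 were more positive.

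For 42 °C, 650 genes had a more positive and 919 a more negative change in IDRm. URA6 was at −2.72 ± 0.20, PDE2 at −2.68 ± 0.19, VIP1 at −2.27 ± 0.15, GCD7 at −2.10 ± 0.16, PAB1 at −1.93 ± 0.10 (edgeR, adjusted p = 6.32e-16) and PMA1 at −1.32 ± 0.10. MIG2 was at 2.54 ± 0.22, HXK1 at 2.46 ± 0.22, CIN5, a stress regulator, at 2.166 ± 0.18 and UBI4 at 1.94 ± 0.10. Ribosome biogenesis genes had 101 more negative changes of 113, or 108 adjusted over the list alone, with a median of −0.77 beside the spread of the 30 °C replicates given above, MAK21 at −1.76 ± 0.14 and UTP23 at −1.77 ± 0.18. General stress genes had 23 more positive of 37, or 25 more positive and 1 more negative adjusted over the list alone, with a median of 0.90 (adjusted p = 0.245 for both with an estimated correlation). HSP104 and SSA4, at 0.22 ± 0.28 and 0.58 ± 0.69, did not pass (edgeR, adjusted p = 0.643 and 0.614), nor did HSP26, HSP82, SSA1, ADH1 and DED1 (adjusted p = 0.556, 0.977, 0.533, 0.06 and 0.481). TEF1, at −0.36 ± 0.12 (edgeR, adjusted p = 0.0254), lost its call when any of 5 libraries was left out (adjusted p of 0.0613 to 0.149), as did HSP12, at 2.005 ± 0.56 (adjusted p = 0.0419; 0.0667 to 0.115 without any of 5 libraries). PGK1, at 0.34 ± 0.09 (edgeR, adjusted p = 0.00668), lost its call without IDRm 30 °C replicate 1 (adjusted p = 0.0733) or IDRm 42 °C replicate 2 (adjusted p = 0.0524). Without IDRm 30 °C replicate 1, 415 were more positive. With library size alone 455 were more positive and 1098 more negative, 29.3% against 41.4% more positive. None of the 18 and 22 list calls in the differences for 40 and 42 °C was kept with an estimated correlation, and 11 and 20 of them passed fry. The difference of the 2 strains' responses to 42 °C was not tested against that to 40 °C.

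Across 4873 genes with at least 10 CPM, the changes of the strains, which share no library, had a Pearson correlation of 0.973 at 40 °C and 0.918 at 42 °C. Genes are not independent replicates, so no p-value is given. The total least squares slope of IDRm on WT was 1.11 at 40 °C and 1.29 at 42 °C, and it ranged from 1.084 to 1.144 and from 1.226 to 1.337 when each library was left out.

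**Figure D3:**
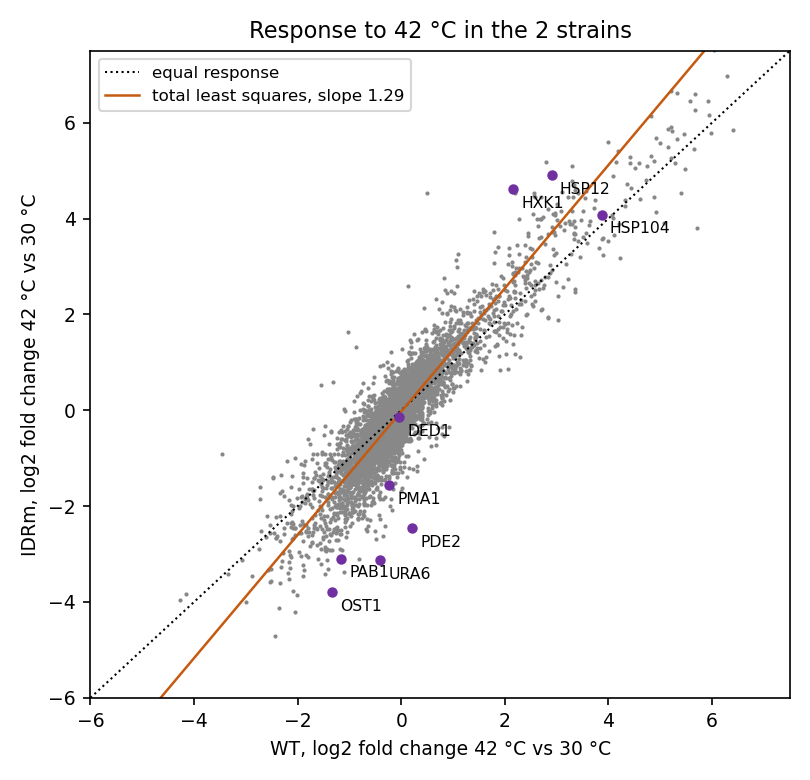
Log2 fold change from 30 to 42 °C of each gene in WT (horizontal axis) and IDRm (vertical axis); grey points are genes, purple points named genes, the dotted line marks equal change and the orange line the total least squares slope of 1.29. PAB1, URA6, PDE2 and OST1 lay below and HXK1 and HSP12 above the dotted line.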

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

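The results below are those in which the change of IDRm with heat differed from the change of WT. The difference of the 2 responses was itself tested, as an interaction in the edgeR fit, and each value is the log2 change in IDRm minus that in WT. Such a value also holds, with its sign turned, any difference between the strains before heating.

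For 40 °C, 218 genes were more positive and 487 more negative. List medians were −0.27 for ribosome-bound and TRiC chaperones, 0.21 for general stress, 0.38 for trehalose and glycogen, −0.38 for ribosomal proteins, −0.50 for ribosome biogenesis and −0.37 for RNA polymerases I and III. They were −0.22 for initiation factors, −0.38 for elongation factors, −0.24 for tRNA synthetases, 0.49 for sulfur genes, 0.21 for oxidative phosphorylation and 1.11 for hexose transporters. Ergosterol genes had −0.27, cell wall −0.13, plasma membrane transport −0.32, phosphate −0.55, a-cell genes 0.37 and the pheromone pathway 0.43. The oxidative phosphorylation call ended without WT 30 °C replicate 1, with a list mean of 0.064 (camera, adjusted p = 0.123), and the cell wall call without WT 40 °C replicate 2 (adjusted p = 0.0543). None of these 18 list calls was kept with an estimated correlation (adjusted p of 0.145 to 0.515, camera). In IDRm against WT, sulfur genes had a median of −0.81 at 30 °C and −0.21 at 40 °C, and ribosome biogenesis genes 0.42 and −0.13. The values of these lists thus largely reflect the difference at 30 °C. So do those of RNA polymerases I and III (0.32 and −0.03), a-cell genes (−0.67 and −0.26) and the pheromone pathway (−0.32 and −0.02). Cell wall genes, at 0.31 and 0.17, were still higher in IDRm at 40 °C. Hexose transporters had 0.08 and 1.41 and ribosomal proteins 0.02 and −0.35, so for these the difference lay mainly at 40 °C.

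The genes named for 40 °C with more positive values were YKR075C at 3.31, FAT3 at 2.12, SUC2 at 1.96, MTH1 at 1.77, MPF1 at 1.73, UBI4 at 1.52, HXT4 at 1.41, MET3 at 1.19, HXT3 at 1.14, HXK1 at 1.00, SER3 at 0.96, MET14 at 0.88, HIS5 at 0.86 and OM45 at 0.85. HXT6, at 2.65, had as few as 1 count at 30 °C, so its value depends on the prior count of the fit and is no bound. More negative were SSB1 at −1.60, ERG2 at −1.55, RPL11A at −1.51, RSA4 at −1.50, ERG13 at −1.49, RPL24B at −1.49, SSF1 at −1.29, ERG20 at −1.29, NOG1 at −1.26, RRP12 at −1.25, RPL4A at −1.21, TIF3 at −1.21 and SAM1 at −1.09. Smaller values were those of PAB1 at −0.92, NIP1 at −0.88, PMA1 at −0.79, OST1 at −0.78, STT3 at −0.60, SEC62 at −0.57, TEF1 at −0.48 and DED1 at −0.32. SSB1, RPL11A, RPL4A, HXT3, HXT6 and TEF1 share sequence with paralogs and are uncertain. At 30 °C UBI4, MET3 and SER3 were at −1.404, −1.777 and −1.475 in IDRm against WT, and their positive values include that difference. PAB1 and PMA1 were at −0.03 and 0.04 there. The calls of DED1, OM45 (adjusted p = 0.131 in edgeR without WT 30 °C replicate 1) and SEC62 (adjusted p = 0.0844 in edgeR without IDRm 40 °C replicate 2) ended when single libraries were left out, and those of HXK1 and TEF1 with library size alone (adjusted p = 0.0515 and 0.0986).

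For 42 °C, 650 genes were more positive and 919 more negative. List medians were 0.32 for heat-inducible chaperones, −0.23 for ribosome-bound and TRiC chaperones, 0.90 for general stress, 0.62 for trehalose and glycogen, 0.38 for antioxidants, −0.19 for ribosomal proteins, −0.77 for ribosome biogenesis and −0.49 for RNA polymerases I and III. They were −0.28 for initiation factors, −0.36 for elongation factors, −0.11 for tRNA synthetases, 0.30 for amino acid biosynthesis, 0.53 for sulfur genes, 0.30 for glycolysis and 0.30 for oxidative phosphorylation. Hexose transporters had 1.11, ergosterol −0.26, translocation and glycosylation −0.23, plasma membrane transport −0.37, histones 0.25, phosphate −0.51 and iron −0.48. Several of these calls ended with 1 library left out (camera). For heat-inducible chaperones the list mean was −0.014 without WT 30 °C replicate 2 (adjusted p = 0.335), so its sign turned, and 0.169 without IDRm 30 °C replicate 1 (adjusted p = 0.0767). Without WT 30 °C replicate 1 the calls of hexose transporters, histones and oxidative phosphorylation ended (camera, adjusted p = 0.0847 for each). The list mean of hexose transporters was then 1.156 against 1.22, that of histones 0.179 against 0.28 and that of oxidative phosphorylation 0.109 against 0.23. The iron call ended without WT 30 °C replicate 1 (list mean −0.229 against −0.38), WT 42 °C replicate 2 (−0.298) or IDRm 30 °C replicate 2 (−0.354). With library size alone it ended too (camera, adjusted p = 0.0657), though the list mean was then −0.463. Glycolysis ended without WT 42 °C replicate 1 (list mean 0.113, adjusted p = 0.2), IDRm 30 °C replicate 1 (adjusted p = 0.0596) or IDRm 42 °C replicate 2 (adjusted p = 0.084, camera). Without genes that share sequence, the calls of hexose transporters (list mean 0.531, camera adjusted p = 0.118) and glycolysis (list mean 0.095, adjusted p = 0.396) ended as well. So did those of ribosome-bound and TRiC chaperones (list mean −0.115, camera adjusted p = 0.194) and histones (adjusted p = 0.101). For histones the list mean was then 0.268 against 0.28, so it hardly moved. None of these 22 list calls was kept with an estimated correlation (adjusted p of 0.245 to 0.597, camera). In IDRm against WT, sulfur genes had a median of −0.81 at 30 °C and −0.21 at 42 °C. Ribosome biogenesis genes had 0.42 and −0.37, and general stress genes 0.34 and 1.35.

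The genes named for 42 °C with more positive values were MIG2 at 2.54, HXT7 at 2.47, HXK1 at 2.46, IGD1 at 2.35, CIN5 at 2.17, CCW22 at 2.08, HSP12 at 2.005, UBI4 at 1.94, ARG1 at 1.21, HIS5 at 1.15, HXT5 at 1.15, SER3 at 1.14, MET3 at 1.14, HXT2 at 1.11, MET14 at 1.00, MET2 at 0.76 and PGK1 at 0.34. More negative were URA6 at −2.72, PDE2 at −2.68, OST1 at −2.44, ERG2 at −2.28, VIP1 at −2.27, IMD4 at −2.27, GCD7 at −2.10, PAB1 at −1.93, UTP23 at −1.77, MAK21 at −1.76, RPL11A at −1.76, NAN1 at −1.66, ERG11 at −1.65 and RPS12 at −1.57. Also more negative were RPS6B at −1.49, TIF3 at −1.43, PMA1 at −1.32, ERG20 at −1.31, STT3 at −1.15, SEC62 at −0.98 and TEF1 at −0.36. HXT7, RPL11A, RPS6B and TEF1 share sequence with paralogs and are uncertain. UBI4, MET3 and SER3 were lower in IDRm at 30 °C, as given above, and their positive values include that difference. The calls of HSP12, MET2, HXT5 (adjusted p = 0.187 in edgeR without WT 30 °C replicate 2), TEF1 (0.119 without the same library) and PGK1 (0.0733 without IDRm 30 °C replicate 1) ended when single libraries were left out.

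The first pattern weighed was the difference between the strains at 42 °C in general stress and ribosome biogenesis genes; of its tests, those on scaling, on the difference at 30 °C and on the 40 °C response were chosen only after the result was seen. The smallest list median over 3 scalings was 0.37 in absolute value. The gap between the lists, 1.717, was 1.67 after thinning all libraries to 3429950 counts. After removing the trend with coding length and GC content it was 1.48. A scaling factor moves all genes of a library alike, so the gap could not test it. Under the 3 scalings the general stress median was 1.237 to 1.346 and the ribosome biogenesis median −0.478 to −0.37. Neither sign thus hung on the scale. Thinning keeps the expected share of each gene, so it tests the library totals alone. The gaps of 1.67 and 1.48 argued against unequal totals and a linear trend with length and GC content as its sources. The gap was 1.67 in the difference of the responses and −0.08 at 30 °C, so it was not present before heating. Both lists were higher in IDRm at 30 °C (medians 0.34 and 0.42), which the gap cannot show. List by list, general stress had 1.35 at 42 °C and 0.90 in the difference of the responses, and ribosome biogenesis −0.37 and −0.77. Across 4873 genes, which are not independent replicates, the strain difference at 42 °C had a correlation of 0.535 with the WT change from 30 to 40 °C. It shares no library with that change. Its rank correlations were −0.151 with the GC content of the 50 nt upstream of the start codon (4860 genes) and −0.318 with coding length. As a hypothesis, the value 0.535 goes with IDRm at 42 °C lying further along the 40 °C response. The value −0.151 describes a weak relation to upstream sequence across genes. Median upstream GC was 32% in general stress genes, 34% in ribosome biogenesis genes and 34% in all tested genes. It thus did not set the ribosome biogenesis genes apart. In genes at least 2-fold higher in IDRm at 42 °C it was 30%, and in those at least 2-fold lower 36%. Given coding length, coding GC and the WT change to 40 °C, the rank correlation with upstream GC was −0.119. Neither relation excludes the other, differences in RNA level were not separable from translation here, and strain background was not tested.

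The second pattern was the lower level of sulfur, pheromone and a-cell genes in IDRm at 30 °C; its tests on growth stage and on shared reads were chosen only after the result was seen, and the latter replaced an earlier test that could not give a result. Reads shared between paralogs were excluded, since no called member shared more than 0.02% of its 28-mers, and a single library was excluded, since each list median kept at least 73.5% of its size when any library was left out. Growth stage at harvest stayed undecided: ribosome biogenesis and general stress genes were both higher, and the general stress median fell to 0.08 without 1 library. A technical or culture-related origin was therefore not excluded.

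The third pattern was the difference in heat-inducible genes between the WT replicates at 30 °C, for which the test of reads carried over from heated libraries was chosen only after the result was seen, and a second set of tests, on strongly induced genes, was chosen after the first results. For the chaperone list the replicates differed by a median of 0.036, with 14 of 25 higher in replicate 2, while the list mean of IDRm against WT was −0.20 without replicate 1 and 0.31 without replicate 2. In the first tests the ratio of gained shares was 1.04 for IDRm at 42 °C, the closest to 1 of the 4 heated groups, with 0.886 for WT at 42 °C, 1.435 for WT at 40 °C and 1.873 for IDRm at 40 °C, so carry-over met its prediction for 2 of 4, while a weak heat response before harvest (general stress median 0.18) and sequencing depth (0.06 after thinning) stayed undecided. On 53 strongly induced genes the second tests left carry-over (ratio 0.45) and a weak heat response (ribosome biogenesis median 0.16) undecided, while thinning left their median difference at 0.93 against 0.942, which argues against depth for these genes. Ribosome biogenesis genes were higher in replicate 2 in 108 of 113 cases, whereas 112 of 113 fell in WT at 40 °C. That direction is opposite to a heat response, while the general stress median of 0.18 goes with one. For the chaperone list depth stayed undecided, and carry-over and a weak heat response stayed open. The IDRm replicates at 30 °C differed in these genes too. Replicate 2 was higher in 22 of 25 chaperones (median 0.22) and 33 of 37 general stress genes (median 0.274). It was also higher in 49 of the 53 strongly induced genes (median 0.517), but in only 1 of 113 ribosome biogenesis genes (median −0.195). The cause was not tested in IDRm.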

How the results depend on the processing

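List calls depended most on the correlation assumed between genes: of 225 list calls among 418 list results, 221 were lost with an estimated correlation. Among the 1359 results for named genes and the 418 list results, none called with all libraries was called in the other direction under the settings run. The cause was not tested for any count or call that changed. The uncalled heat-inducible chaperones in IDRm against WT at 30 °C were called lower without WT 30 °C replicate 1 and higher without replicate 2.

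At least 2-fold, WT had 1170 higher and 1066 lower genes at 40 against 30 °C, 836 and 495 at 42 against 30 °C, and 607 and 421 at 42 against 40 °C. In IDRm these were 1257 and 1210, 1032 and 900.0, and 537 and 351. IDRm against WT had 38 and 48 at 30 °C, 74 and 72 at 40 °C and 145 and 215 at 42 °C, and the differences of responses 51 and 60 for 40 °C and 123 and 223 for 42 °C.

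Tested against 1.5-fold with glmTreat, a test added after seeing the data, WT had 1333 higher and 1359 lower, 889 and 723, and 744 and 606 genes for 40 against 30, 42 against 30 and 42 against 40 °C. IDRm had 1416 and 1481, 1163 and 1161, and 637 and 459. IDRm against WT had 14 and 24 at 30 °C, 58 and 77 at 40 °C and 176 and 251 at 42 °C, and the differences of responses 21 and 42 for 40 °C and 80 and 204 for 42 °C.

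Library size alone gave 2620 higher and 921 lower genes for WT at 42 against 40 °C and 974 lower for IDRm. With only the 4 libraries of the comparison, IDRm against WT at 30 °C had 325 higher and 256 lower. DESeq2 gave 331 and 156 there, 476 lower for IDRm against WT at 40 °C, 740.0 higher at 42 °C, and 117 and 310.0 more positive genes in the differences of responses for 40 and 42 °C.

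With single libraries left out, IDRm against WT at 30 °C had 231 to 549 higher and 136 to 401 lower genes, at 40 °C 340.0 to 453 higher and 501 to 680 lower. The differences of responses had 119 to 278 more positive and 307 to 521 more negative genes for 40 °C, and 415 to 738 more positive for 42 °C.

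The deviations of libraries with the same replicate number had correlations of −0.18 to 0.20 over 3976 genes. Between groups of the same strain they were −0.02 to 0.09. The replicates share only a number in the labels, and whether it also marks a shared culture stayed open. In comparisons within a strain and in the differences of responses, a block was fitted for that number within each strain. For IDRm against WT the block was the number alone. Neither moved a count of calls by more than 1.5 times. The block within each strain gave 246 more positive and 538 more negative genes in the difference for 40 °C. With the block within each strain 5 list calls ended and 7 began, and with the number alone no list call changed. At 40 against 30 °C in WT, hexose transporters (adjusted p = 0.122) and mitochondrial chaperones (0.105) ended, and mitochondrial ribosomal proteins (0.0329) and the tricarboxylic acid cycle (0.0369) began. At 42 against 30 °C in WT, mitochondrial chaperones (0.0667) and endoplasmic reticulum folding (0.0536) ended and mitochondrially encoded genes (0.0159) began (all camera).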

Other observations

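In WT at 42 °C, 6 of the 35 genes of the proteasome list rose, among them its transcription factor RPN4 by 4.11 ± 0.09, and 13 fell, with a median of −0.06 and a mean of 0.03. Mitochondrially encoded genes, which are translated by mitochondrial ribosomes, rose in 5 of 8 cases at 42 °C, or 6 adjusted over the list alone, with a median of 1.36, COX2 at 2.10 ± 0.17 and ATP6 at 2.28 ± 0.31. That list did not pass with all libraries (camera, adjusted p = 0.0747) and passed without WT 42 °C replicate 2 (adjusted p = 0.00492). HTA1, histone H2A, rose by 1.28 ± 0.07 at 40 °C and 1.18 ± 0.07 at 42 °C.

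DBP1, the paralog of DED1, had 8.102 CPM in WT and 8.547 CPM in IDRm at 30 °C, and 21.7 and 35.64 CPM at 40 °C. It was singled out after the data had been seen. Ribosome biogenesis genes differed between the replicates of a strain at 30 °C: the second replicate was higher in 108 of 113 genes in WT and in 1 of 113 in IDRm, so that the 30 °C libraries of a strain varied in this list. At 42 °C ribosomal proteins took 16.5% of the counts in WT and 13.4% in IDRm, and general stress genes 1.74% and 3.16%.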
